A study of Homo sapiens with 9 samples.

How the data were processed

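Gene expression was measured with 9 single-channel Affymetrix whole-transcript arrays of NCCIT, a human embryonal carcinoma cell line that resembles pluripotent cells and forms embryoid bodies (floating aggregates that begin to differentiate) when it cannot attach. According to the labels, 1 array came from undifferentiated cells and 8 from embryoid bodies kept with or without 50 mM ethanol, with or without an additive abbreviated as FA, for 7 or 21 days. The meaning and dose of FA are not given in the sources used here, so it is called FA throughout. Each condition had 1 array, and nothing in the labels said whether the arrays came from separate cultures.

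Total RNA was extracted with Trizol and labelled as biotinylated cDNA, per the labels' protocols. The deposited values were log2 expression values made by the authors with RMA (background correction, quantile normalization and a summary per transcript cluster) in Affymetrix Expression Console 1.3.1, per the submitters' processing notes. The base of the logarithm was not written in a label and was inferred from the values, which lay between 2.49 and 14.3 with array medians from 7.67 to 7.76. RMA pulls the arrays toward a common distribution, so a change that shifted most transcripts together would not be seen, and it compresses differences of dim genes. The genome build of the authors' annotation is not given in the sources used here, and no coordinates are reported.

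The table held 33297 transcript clusters. The platform annotation paired 19460 clusters with 1 gene symbol and 1754 with several, and 12083 were unnamed here. Of the clusters with 1 symbol, the Entrez ID of 19429 was found in the RefSeq gene table, and 0 symbols changed through it. Genes were named only from clusters with 1 symbol, which gave 18417 genes. For the 769 genes with more than 1 cluster, the cluster with the highest mean over the 9 arrays was used, with the mean of all clusters as an alternative. A gene was tested if its highest value over the 9 arrays exceeded the median of all values (7.71), which kept 12254 genes and removed 6163. No 2 arrays held the same values throughout.

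The 8 embryoid body arrays form a layout in which ethanol, FA and day are each present in all combinations. One additive model per gene was fitted over the 9 arrays with limma 3.58.1 (lmFit and eBayes) and statmod 1.5.0 in R 4.3.3, with terms for ethanol, FA and day and a separate term for the undifferentiated array. Effects are averages over the matched conditions, so that the ethanol effect is the mean of 4 differences between arrays that share day and FA. The fit had 4 residual degrees of freedom and a prior of 3.94. Its residual stands in for replicate error and also holds any true interaction between ethanol, FA and day. P-values therefore measure only the spread between these arrays, which may be technical. They were adjusted with the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The differentiation effect is the untreated embryoid body level of the additive fit, averaged over both days, minus the undifferentiated array, which was assumed to vary like the others. That level is estimated from all 8 embryoid body arrays, those with ethanol or FA included, and is not the mean of the untreated arrays. Each interaction was tested by adding its term to the model, which left 3 residual degrees of freedom. Differences between 2 single arrays have no test and are given as values, with counts of genes at least 2-fold apart. The number of arrays limits the precision of every value.

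The comparisons, the alternatives and 29 gene lists (markers of pluripotency and of cell lineages, signalling pathways, metabolism and stress) were fixed before the data were examined. Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 29 lists of an effect. In single pairs a list's median was ranked among 10000 random lists of the same size matched on mean expression. Random lists were drawn gene by gene and do not keep genes that move together, so a list of such genes ranks as extreme more easily. Shares of genes from transcription factor families, recognised by symbol, were compared with all other genes by two-sided Fisher's exact tests across genes. The genes named in the text were, for each of ethanol, FA, day and differentiation, the 12 with the largest difference in each direction among those past the threshold with the same sign in all 4 pairs (for differentiation, on both untreated days). Where fewer passed, genes with the same sign in all 4 pairs were added as values. The rule also took the 10 largest differences in each direction of the day 7 pair without FA, the 5 largest interactions in each direction, and up to 4 members of each list with the largest effect. Small RNAs and genes with provisional names were passed over. Any other gene named was chosen after its values were seen, as said there.

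The fits were tested on simulated data with the real genes' fitted levels and with spreads drawn at random from the fitted prior distribution. Simulated errors were independent between genes and arrays, with no interaction and no deviating array. The rates that follow hold for such data and are not the error rate of the real calls. For the ethanol effect, over 5 runs on 12254 genes, 89.2% of genes changed 1.5-fold and 99.0% of genes changed 2-fold were recovered, and 5.43% of the calls were false. The alternatives were no filter and a stricter filter on dim genes, quantile normalization or median centring of the deposited values, the mean of all clusters of a gene, eBayes with trend and robust options, the matched pairs as a block, fits without covariates or with all pairwise interactions, other fold limits, other gene list tests, and leaving out each array in turn.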

Results

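The series was designed to profile expression in embryoid bodies of the human embryonal carcinoma line NCCIT formed in the absence or presence of ethanol, with transcription factors named as the target. It held 1 array of undifferentiated cells and 8 arrays of embryoid bodies. At day 7 and at day 21 there was 1 array each without addition, with 50 mM ethanol, with FA, and with both. No condition was replicated, so every tested effect rests on averages over matched arrays and differences within a single pair have no test. The 4 arrays at day 21 correlated with each other at a mean r of 0.991 to 0.993. At day 7 the array with ethanol and no FA stood somewhat apart, with a mean r of 0.983 with the other day 7 arrays, against 0.989 to 0.990 for the other 3.

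Relative to undifferentiated cells, 13 of 24 pluripotency genes fell and 8 of 14 retinoic acid signalling genes rose in embryoid bodies, with larger medians at day 21 than at day 7, while HOX genes were higher at day 21 alone. Effects use the untreated embryoid body level of the additive fit, averaged over the 2 days, unless a day is given. The largest increases included the homeobox cofactor genes MEIS2 (log2 difference 2.75 ± 0.19, SE of the fit) and MEIS1 (2.62 ± 0.22). The retinoic acid receptor gene RARB rose by 2.57 ± 0.11, with the retinoid enzyme genes DHRS3 (2.38 ± 0.11) and CYP26A1 (2.24 ± 0.12) close behind. TMEM45A (2.81), IGFBP5 (2.71), which codes for a binding protein of insulin-like growth factors, and CP (2.53), which codes for the copper carrier ceruloplasmin, also rose. Further increases were in DNAH11 (2.44), HOXB1 (2.33), HOXB2 (2.33) and LAMP5 (2.23). MEIS1, RARB, CP, HOXB1 and LAMP5 are also among the largest increases between day 7 and day 21 given below, so their averages mostly reflect day 21. The largest decreases were in RHD (-2.44 ± 0.30), the rhesus blood group D antigen gene, CHAC1 (-2.14 ± 0.15), which codes for a glutathione-degrading enzyme, and HHLA1 (-1.90 ± 0.15). PMAIP1 (-1.87), a p53-regulated cell death gene, ALDH1L2 (-1.87), a mitochondrial folate enzyme gene, GPR50 (-1.82) and the cystine transporter gene SLC7A11 (-1.80) also fell. GNG4 (-1.75), the galanin gene GAL (-1.71), S100A11 (-1.69), ZCCHC12 (-1.69) and the serine synthesis gene PSAT1 (-1.65) completed the named decreases. In limma, 3449 of 12254 genes passed the Benjamini-Hochberg adjusted threshold, 1345 higher and 2104 lower in embryoid bodies, or 1083 higher and 2586 lower with each array centred on its median. Limma's adjusted p for these named genes lay between 5.0e-05 and 0.00155.

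Several fixed groups of genes differed between untreated embryoid bodies and undifferentiated cells, some of them at day 21 alone. Of 18 tested HOX genes, which set position along the body axis, 16 rose and 0 fell in the average of the days, with HOXA2 at 2.45 and HOXB3 at 2.13 (16 adjusted over the list alone). That rise came from the day 21 array, where the list median was 2.36 with 18 of 18 above 0, whereas at day 7 it was -0.10 with 6 of 18 above 0 and HOXA2 at -0.37. Of 14 retinoic acid signalling genes, 8 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 0.18 at day 7 and 2.66 at day 21. Of 19 hypoxia and glycolysis genes, 14 rose and 0 fell, with the glycolytic regulator genes PFKFB4 at 1.86 and PFKFB3 at 1.58, the collagen hydroxylase gene P4HA1 at 1.67 and the angiogenic factor gene VEGFA at 1.65 (15 adjusted over the list alone). Of 24 pluripotency genes, 13 fell and 0 rose, with the DNA methyltransferase gene DNMT3B at -1.53, DPPA3 at -1.50, PRDM14 at -1.49 and L1TD1 at -1.36 (15 adjusted over the list alone), and a median of -0.18 at day 7 and -1.01 at day 21. POU5F1 and NANOG were not analysed here because neither had a transcript cluster of its own. Of 22 folate and one-carbon genes, 15 fell and 1 rose, with the serine synthesis gene PSPH at -1.31 and MTHFD2 at -1.20 (15 and 1 adjusted over the list alone). Of 20 genes of the ER stress and amino acid response, 11 fell and 2 rose, with the asparagine synthetase gene ASNS at -1.48 and the lipoprotein receptor gene VLDLR at 1.11 (12 and 2 adjusted over the list alone). Of 17 oxidative stress genes, 9 fell and 1 rose, among them the quinone reductase gene NQO1 at -1.34 (12 and 1 adjusted over the list alone). Of 29 cell cycle genes, 16 fell, with the cyclin gene CCNE1 at -0.92 (17 adjusted over the list alone). Camera at the preset correlation passed these 8 lists, together with neural progenitor, mesenchyme and matrix, and cholesterol synthesis genes, at adjusted p from 7.5e-13 (HOX genes) to 0.0399 (neural progenitor). None of the 11 held when the correlation was estimated, the lowest being retinoic acid signalling at adjusted p = 0.125 with an estimated correlation, and hypoxia and glycolysis at adjusted p = 0.385 with an estimated correlation. In the neural progenitor list 7 of 19 genes rose and 2 fell (7 and 2 adjusted over the list alone), in the mesenchyme and matrix list 5 of 16 rose and 1 fell (6 and 1 adjusted over the list alone), and in the cholesterol synthesis list 7 of 16 fell (7 adjusted over the list alone). The cholesterol decrease was in the day 21 array (median -0.68), while at day 7 the list was slightly higher than in undifferentiated cells (median 0.13, 10 of 16 above 0). The median, mean and camera direction did not share a sign for heart and muscle, early mesoderm, endoderm, p53 target, WNT, DNA methylation and chromatin, imprinted and interferon genes, none of which passed. All of these differences rest on a single undifferentiated array, and without the untreated day 7 array 2107 genes passed.

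More genes passed the test between day 7 and day 21 than in any other comparison. The count does not rank the size of the changes, because the median SE was 0.064 for day and 0.106 for differentiation. Between single untreated arrays, 761 genes were at least 2-fold apart from day 7 to day 21. From undifferentiated cells the numbers were 203 to day 7 and 878 to day 21. Between day 7 and day 21 FRZB, which codes for a secreted WNT antagonist, rose most, by a log2 difference of 5.50 ± 0.14. It was followed by HOXA2 (5.19 ± 0.10), MEIS1 (4.81 ± 0.14), RARB (4.66 ± 0.07), SKAP2 (4.44 ± 0.14) and the neural and eye patterning gene PAX6 (4.32 ± 0.11). HOXC5 (4.17), CP (4.04), PDZRN3 (4.01), HOXB3 (3.93), HOXB1 (3.92) and LAMP5 (3.88) were the other increases named by the rule. RHD (-3.50 ± 0.18), MAS1 (-3.23 ± 0.11) and TRIML2 (-3.09 ± 0.11) fell most. HHLA1 fell next. RPL39L (-2.63), GLB1L3 (-2.62), the germline and pluripotency regulator gene PRDM14 (-2.58), VAT1L (-2.54), L1TD1 (-2.50), VIPR2 (-2.41), the retinol esterification gene LRAT (-2.31) and TPTEP1 (-2.28) fell as well. Limma with Benjamini-Hochberg adjustment passed 5995 of 12254 genes, 3224 higher and 2771 lower at day 21, of which 618 were at least 2-fold apart, and adjusted p for the named genes lay between 7.9e-09 and 1.65e-04. With each array centred on its median the split was 3859 higher and 2093 lower.

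All 18 tested HOX genes were higher at day 21 and 17 of them rose over all genes tested (18 adjusted over the list alone). HOX genes dim on all arrays, such as HOXC9 and HOXD10, were removed by the filter. A HOX gene dim at day 7 was tested only if it was brighter on another array, which favours genes that rose. Of 14 retinoic acid signalling genes 11 rose and 0 fell (11 adjusted over the list alone), with the retinoic acid hydroxylase genes CYP26B1 at 3.65 and CYP26A1 at 3.41. Of 24 pluripotency genes 19 fell and 2 rose (19 and 2 adjusted over the list alone), with the NODAL co-receptor gene CRIPTO at -2.27 and DNMT3B at -2.14. Of 16 cholesterol synthesis genes 15 fell and 0 rose (16 adjusted over the list alone), with HMGCS1 at -1.41, INSIG1 at -1.41 and DHCR7 at -1.11. Of 11 neuron genes 6 rose and 2 fell (6 and 2 adjusted over the list alone), with the adhesion molecule gene NCAM1 at 2.31, the migration gene DCX at 1.66 and the synaptic gene SNAP25 at 1.46. Camera passed these 5 lists at the preset correlation, with adjusted p of 3.5e-13, 1.79e-06, 2.73e-07, 2.73e-07 and 0.0480 in that order. None held with an estimated correlation, where the lowest was retinoic acid signalling at adjusted p = 0.156 with an estimated correlation, and HOX and neuron genes had adjusted p = 0.366 with an estimated correlation.

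The other 24 lists did not pass camera for day, and most held members that moved in both directions. Genes that rose and fell numbered 7 and 3 of 19 among neural progenitor genes, 3 and 3 of 10 in neural crest, 3 and 2 of 12 in early mesoderm and 4 and 2 of 12 in endoderm. They numbered 1 and 4 of 9 in heart and muscle, 1 and 3 of 7 in endothelium and blood, 1 and 1 of 5 in trophoblast, 6 and 5 of 16 in mesenchyme and matrix, and 1 and 0 of 2 in germ cell genes. None of 3 liver and yolk sac genes passed. The numbers were 7 and 11 of 22 for folate and one-carbon, 5 and 3 of 17 for oxidative stress and 3 and 9 of 20 for ER stress and amino acid response. They were 1 and 3 of 9 for ethanol and aldehyde metabolism, 3 and 6 of 19 for hypoxia and glycolysis, 5 and 2 of 16 for p53 target and 4 and 12 of 29 for cell cycle genes. They were 1 and 5 of 11 for WNT, 8 and 6 of 16 for BMP and TGF-beta and 2 and 7 of 12 for Notch genes. For the last lists they were 6 and 2 of 18 for DNA methylation and chromatin, 5 and 3 of 11 for imprinted, 1 and 6 of 16 for immediate early and 2 and 0 of 5 for interferon genes. Adjusted over the list alone, 10 neural progenitor genes rose and 4 fell, 1 early mesoderm gene fell, 8 folate and one-carbon genes and 5 cell cycle genes rose, 8 hypoxia and glycolysis genes fell, 3 Notch genes and 0 immediate early genes rose, and the other numbers stayed as given. Single genes in these lists included the heart and muscle regulator gene MEF2C (3.18), the lymphatic and hepatic regulator gene PROX1 (3.17), the ligand gene WNT5A (2.52), the growth factor receptor gene PDGFRA (2.67), TFAP2A (-2.10) and MYC (-1.13). The median, mean and camera direction did not share a sign for heart and muscle, endoderm, mesenchyme and matrix, oxidative stress, WNT and Notch genes.

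**Figure D1:**
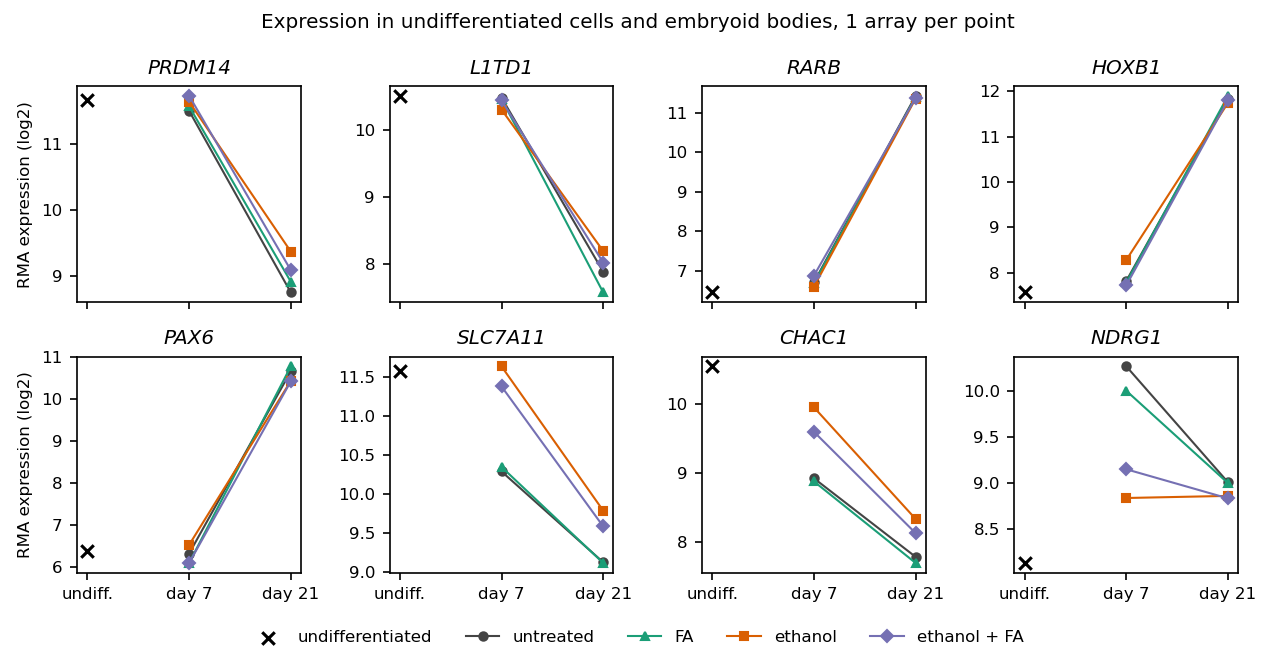
RMA expression (log2, vertical axis) of 8 genes in undifferentiated cells and in embryoid bodies at day 7 and day 21, with 1 array per point and a line joining the arrays of a treatment. PRDM14 and L1TD1 were lower and RARB, HOXB1 and PAX6 higher at day 21, while SLC7A11 and CHAC1 were higher with ethanol than without it on both days.

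With ethanol 69 genes rose and 15 fell, most of them by less than 1.5-fold. SLCO4C1 (transcript cluster 8113369), which codes for an organic anion transporter, had the largest ethanol effect at 1.13 ± 0.08 (SE of the fit), a 2.19-fold increase. The monocarboxylate transporter family genes SLC16A14 (0.92 ± 0.15) and SLC16A9 (0.72 ± 0.09) also rose. So did the cystine and glutamate exchanger gene SLC7A11 (0.88 ± 0.13) and the large neutral amino acid transporter gene SLC7A5 (0.85 ± 0.10). Smaller increases were in the choline transporter-like gene SLC44A2 (0.72 ± 0.09) and in the neutral amino acid transporter gene SLC1A4 (0.65 ± 0.10). ALDH1L2 (0.71 ± 0.07) and CHAC1 (0.68 ± 0.09) rose, as did the sodium channel subunit gene SCNN1A (0.70 ± 0.06), ODC1 (0.64 ± 0.10), which codes for the rate-limiting enzyme of polyamine synthesis, and the metalloproteinase inhibitor gene TIMP4 (0.62 ± 0.07). The largest decreases were in the protocadherin beta adhesion genes PCDHB14 (cluster 8108744, -0.89 ± 0.10), PCDHB16 (-0.57 ± 0.06) and PCDHB9 (-0.52 ± 0.08), in IGFBP7 (-0.59 ± 0.09) and in the chemokine receptor gene CXCR4 (-0.53 ± 0.06).

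Smaller decreases were seen in the semaphorin receptor gene PLXNC1 (-0.51), the protease inhibitor gene A2M (-0.47), SLC5A9 (-0.37), the adenylate cyclase gene ADCY2 (-0.36), PREX1 (-0.31), the mitotic ubiquitin enzyme gene UBE2C (-0.29) and the cyclophilin gene PPIA (-0.29). Protocadherin beta genes are near-identical neighbours, and their probes can share signal. In limma with Benjamini-Hochberg adjustment 84 of 12254 genes passed, 69 higher and 15 lower with ethanol. Limma's adjusted p for the named genes lay between 0.00698 and 0.0484. All 84 had the same sign in all 4 pairs, their folds ran from 1.22 to 2.19, and 19 were at least 1.5-fold apart. SLC7A5, SLCO4C1 and PCDHB14 were the 3 genes that differed at least 1.5-fold in the same direction in all 4 pairs. The stricter filter on dim genes removed PCDHB14 and left the 2 that were higher. Without the day 7 array with ethanol and no FA 212 genes passed (160 higher, 52 lower), without the day 7 array with ethanol and FA 129 (76 higher, 53 lower), without the day 21 FA array 3 and without the untreated day 21 array 2. None passed without either ethanol array of day 21, the FA array of day 7 or the untreated array of day 7, so the number of calls rests on single arrays, and it was 0 in a fit without the day and FA terms.

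**Figure D2:**
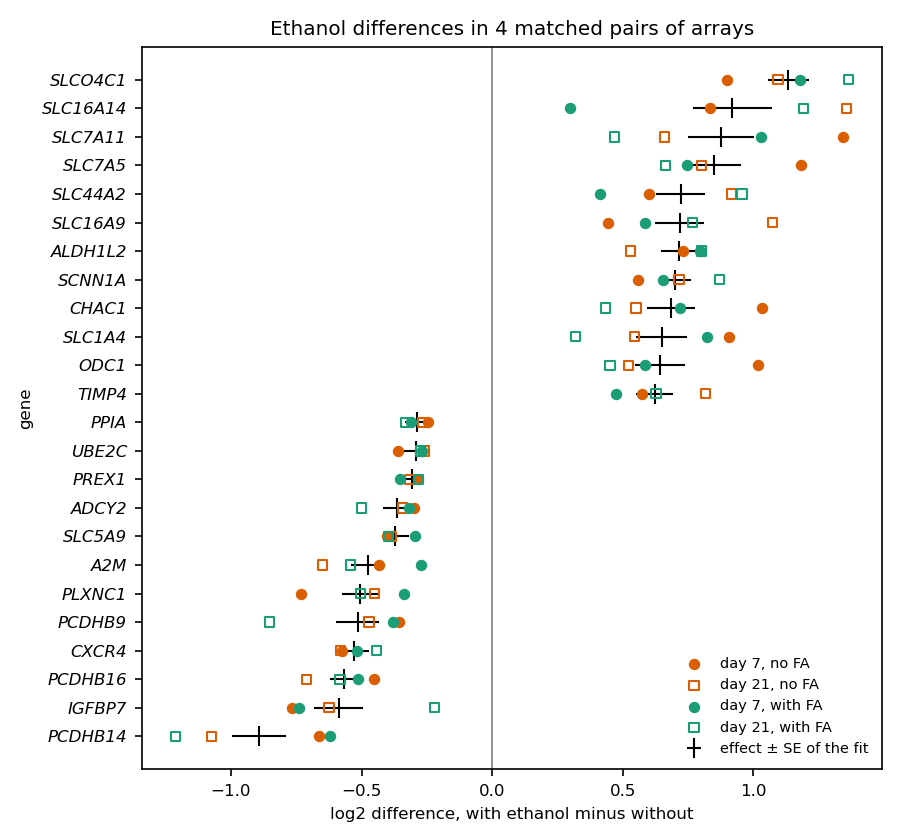
Ethanol differences (log2, with ethanol minus without, horizontal axis) of the 12 genes with the largest increase and the 12 with the largest decrease past the threshold. Coloured points are the 4 matched pairs of arrays, and black bars the effect ± its SE in the fit. All 4 pairs of each gene lie on the same side of 0, and those of SLCO4C1 run from 0.90 to 1.36.

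The lists that passed camera at the preset correlation for ethanol were those of hypoxia and glycolysis, oxidative stress, and folate and one-carbon genes. All 19 hypoxia and glycolysis genes were lower on average, with the stress gene NDRG1 at -0.65 ± 0.19, ANKRD37 at -0.57 ± 0.17, the histone demethylase gene KDM3A at -0.52 ± 0.16 and PFKFB4 at -0.51 ± 0.16, but 0 passed over all genes tested and 10 passed adjusted over the list alone. Camera in limma gave adjusted p = 9.8e-12 for the list, adjusted p = 0.675 with an estimated correlation, and the rotation test fry adjusted p = 0.141, whereas fry passed oxidative stress genes at adjusted p = 0.00355. The list median was -0.50 at day 7 without FA, which involves the array that stood apart, -0.21 at day 7 with FA, -0.12 at day 21 without FA and -0.17 at day 21 with FA. Without that array the list's median effect was -0.15 with 4 genes lower over all genes tested, and fry passed it at adjusted p = 0.0441. Of 17 oxidative stress genes 1 rose, SLC7A11, and 4 passed adjusted over the list alone. Other members were the sulfiredoxin gene SRXN1 at 0.37 and the metallothionein genes MT2A at 0.35 and MT1X at 0.23, and camera gave adjusted p = 0.00169 (adjusted p = 0.413 with an estimated correlation). Of 22 folate and one-carbon genes 1 rose, ALDH1L2, and 8 were higher and 1 lower adjusted over the list alone, with PSAT1 at 0.47, PSPH at 0.36 and MTHFD2 at 0.35. This list passed camera at adjusted p = 0.0397 (adjusted p = 0.675 with an estimated correlation), and at adjusted p = 0.0693, no longer past the threshold, without the array that stood apart.

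**Figure D3:**
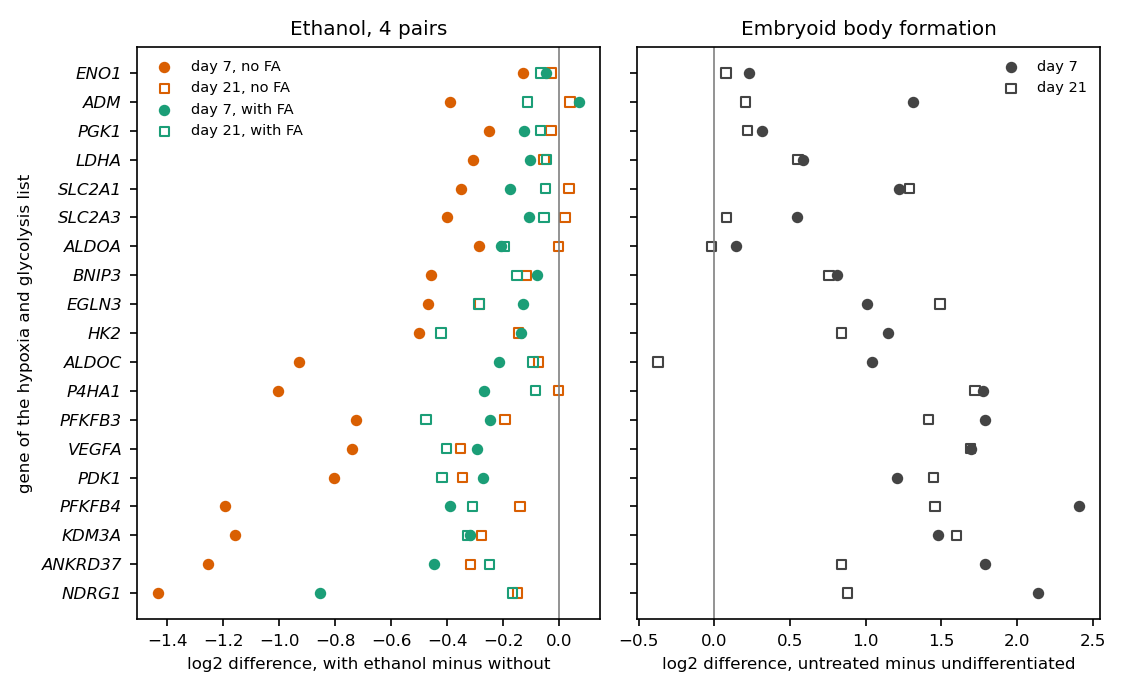
Differences (log2) of the 19 measured hypoxia and glycolysis genes, on the left between arrays with and without ethanol in 4 matched pairs and on the right between untreated embryoid bodies and undifferentiated cells, with 1 point per pair of arrays. With ethanol all 19 genes lie below 0 at day 7 without FA and at day 21 with FA, 18 at day 7 with FA and 16 at day 21 without FA.

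Other lists did not pass camera for ethanol with all arrays, with adjusted p from 0.0866 (pluripotency, median 0.11) to 0.997 (BMP and TGF-beta). Without the array that stood apart 4 of them did, pluripotency (median 0.09, adjusted p = 0.0288) and cholesterol synthesis genes (0.08, adjusted p = 0.0288) as higher and neural progenitor (-0.07, adjusted p = 0.0335) and HOX genes (-0.10, adjusted p = 0.0288) as lower, and none held with an estimated correlation (lowest adjusted p = 0.784 with an estimated correlation). Single members rose in several of them. They were the pluripotency factor gene TFCP2L1 (0.42 ± 0.06), the neuronal genes INA (0.60 ± 0.10) and NCAM1 (0.47 ± 0.05), and the neural crest gene SNAI2 (0.51 ± 0.08). The VEGF receptor gene FLT1 (0.60 ± 0.10), SFRP1 (0.52 ± 0.07), which codes for a WNT antagonist, and CHAC1 in the ER stress and amino acid list rose too, while CXCR4 fell in the endoderm list. Limma's adjusted p for these genes lay between 0.0227 and 0.0498. Adjusted over the list alone, 2 pluripotency, 3 neuron, 2 neural crest, 1 endothelium and blood, 1 endoderm, 1 trophoblast, 1 mesenchyme and matrix, 2 cell cycle, 1 cholesterol synthesis and 1 WNT gene were higher. Lower ones were 2 neural crest, 1 heart and muscle, 1 endoderm and 2 Notch genes. Also adjusted over the list alone, 6 of 20 ER stress and amino acid genes were higher, among them HERPUD1 (0.41) and SESN2 (0.36), and 0 of 9 ethanol and aldehyde metabolism genes passed, with ALDH1A1 at -0.41 ± 0.24 and ALDH2 at 0.11 ± 0.05. None of 18 HOX genes and, over all genes tested, none of 14 retinoic acid signalling genes passed (0 and 2 adjusted over the list alone). The median, mean and camera direction did not share a sign for heart and muscle, mesenchyme and matrix, ethanol and aldehyde metabolism, and immediate early genes.

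The comparison named in the study's design, day 7 with and without ethanol in the absence of FA, rests on 1 array of each kind. The largest increases were in SHISA3 (1.61), SLC7A11 (1.34), LRAT (1.29), SLC7A5 (1.18), CHAC1 (1.03) and the MAP kinase phosphatase gene DUSP6 (1.03). They were followed by ODC1 (1.02), SLC1A4 (0.91), SLCO4C1 (0.90) and the mechanosensitive channel gene PIEZO2 (0.90). The largest decreases were in the endothelial phosphatase gene PTPRB (-2.07), the glycogen branching enzyme gene GBE1 (-1.48), NDRG1 (-1.43), TMEM45A (-1.32) and PPFIA4 (-1.31). UPK1A (-1.29), the sterol regulator gene INSIG2 (-1.27), DNAH11 (-1.26), ADAMTS20 (-1.25) and ANKRD37 (-1.25) were next. In this pair 7 genes were at least 2-fold higher and 35 at least 2-fold lower with ethanol. The numbers were 6 and 4 at day 21 without FA, 5 and 2 at day 7 with FA, and 4 and 5 at day 21 with FA. The ethanol array of the day 7 pair without FA is the one that stood apart. The larger number of decreases in that pair can therefore not be told apart from a deviation of that array. Across genes, which are not independent replicates, the ethanol differences of pairs that share no array correlated at Pearson's r from 0.18 to 0.65. The same sign in all 4 pairs was found for 3610 genes (29.5%). Independent signs centred on 0 would give 12.5%, but genes move together, so that value is no tested chance level.

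No single gene passed the test for FA. Genes with the same sign in all 4 FA pairs included DMRT3 (0.24 ± 0.05), HOXB4 (0.22 ± 0.07), SMIM45 (0.18 ± 0.05), CUEDC2 (0.15 ± 0.06) and WLS (0.14 ± 0.04), which codes for a WNT secretion factor, as higher values. Others were HES3 (0.13 ± 0.07), CUX1 (0.12 ± 0.05), CROCC (0.12 ± 0.05), SGSM2 (0.11 ± 0.04), CRYGC (0.11 ± 0.05), ZNF219 (0.09 ± 0.05) and the pseudogene ALG1L1P (0.20 ± 0.09). Lower values were those of ALDH1L2 (-0.27 ± 0.07), SPRY4 (-0.27 ± 0.17), the kinase gene SGK1 (-0.24 ± 0.05), LRRTM3 (-0.23 ± 0.10), NCR3LG1 (-0.23 ± 0.05) and the BMP receptor gene BMPR1B (-0.21 ± 0.06). Further lower values were those of MRAP2 (-0.21 ± 0.05), GNG11 (-0.20 ± 0.05), SULF1 (-0.20 ± 0.07), SPON1 (-0.19 ± 0.05), PRDM1 (-0.19 ± 0.11) and DCLK1 (-0.17 ± 0.11). Limma passed 0 of 12254 genes, with a smallest adjusted p of 1.00 and 121 genes at an unadjusted p under 0.05, where chance alone gives 613. At day 7 without ethanol, the arrays with and without FA were the closest pair, with an SD of differences across genes of 0.09 and 0 genes 2-fold apart. Folate and one-carbon genes were slightly lower with FA (median -0.04, 4 of 22 above 0, camera adjusted p = 0.0137) and hypoxia and glycolysis genes slightly higher (median 0.05, 17 of 19 above 0, camera adjusted p = 0.0292). In both lists 0 members passed over all genes tested and 0 adjusted over the list alone, and both had adjusted p = 0.923 with an estimated correlation. The hypoxia and glycolysis rise was in 1 pair, day 7 with ethanol (median 0.31), which uses the array that stood apart, and the other 3 pairs had medians of -0.06, -0.01 and -0.07. Without that array its median was -0.06 and neither list passed (camera adjusted p = 0.0580, and 0.619 for folate and one-carbon genes), while neural progenitor, endothelium and blood, liver and yolk sac, HOX and cholesterol synthesis genes did (camera adjusted p from 0.00227 to 0.0437, and adjusted p = 0.946 with an estimated correlation for each). The FA differences had the same sign in all 4 pairs for 833 genes (6.80%, against 12.5% for independent signs). Across genes, FA differences at day 7 with ethanol correlated at r of -0.56 and -0.52 with those at day 21 without and with ethanol. Between the 2 day 7 pairs r was -0.16, and between the 2 day 21 pairs 0.55. FA differences at day 7 without ethanol correlated at 0.12 and 0.18 with those at day 21 without and with ethanol. The median, mean and camera direction did not share a sign for neuron, early mesoderm, heart and muscle, mesenchyme and matrix, oxidative stress, p53 target, WNT and interferon genes.

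SHISA3 was the single gene whose ethanol difference passed the test for a change between the days. Ethanol differences of this Shisa family gene were 1.61 and 1.35 at day 7 without and with FA, and -0.24 and -0.18 at day 21, an interaction of -1.69 ± 0.11 (limma adjusted p = 0.0358). Its level was 7.49 and 7.53 in the day 7 arrays without ethanol and 9.10 and 8.89 in those with it, and between 9.12 and 9.41 in the 4 day 21 arrays. Without the filter on dim genes adjusted p was 0.0519, and after quantile normalization 0.0532. The ethanol by day model passed 1112 genes without the day 7 array with ethanol and FA, 329 without the day 7 array with ethanol alone, and 0 when any of the other 6 embryoid body arrays was left out, so the number of calls depends on single arrays. The ethanol by FA and FA by day interactions passed 0 genes in limma, with 100 and 1496 genes at an unadjusted p under 0.05.

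Few genes of transcription factor families, the class named in the study's title, were among the ethanol calls. Of 598 tested genes from transcription factor families 1 passed, SNAI2, or 0.167%, against 83 of 11656 other genes or 0.712% (Fisher's exact test across genes, two-sided p = 0.194, adjusted p = 0.807 over 18 comparisons). The unadjusted Fisher's exact p was 0.0452 with a stricter filter on dim genes and 0.0313 after quantile normalization. TFCP2L1 (0.42) and EBF3 (0.38), transcription factor genes outside these families, also passed, and EBF3 is named after its values were seen. For day, 48.7% of the 598 family genes passed, against 48.9% of other genes (Fisher's exact adjusted p = 1.00). Of the 217 that are not ZNF genes, among them the HOX, MEIS, PAX and RAR genes given above, 59.0% passed (Fisher's exact adjusted p = 0.0352). For differentiation, 21.2% of the 598 passed, against 28.5% of other genes (Fisher's exact adjusted p = 0.00158), and 32.3% of the 217 (Fisher's exact adjusted p = 0.807), so the lower share came from ZNF genes. Genes are not independent of each other, so these p-values are descriptive.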

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

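The tests on splits of the arrays were planned, whereas the test of exchanged labels, the balance of the splits and the tests that leave out the day 7 array with ethanol and no FA were chosen only after the result was seen.

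Ethanol differences of SHISA3 changed between the days, with an interaction of -1.69 in limma. At the preset correlation, camera also gave a different ethanol effect on day 21 than on day 7 for 8 fixed lists, with median interactions of 0.21 for pluripotency, -0.10 for neural progenitor, 0.12 for mesenchyme and matrix, -0.29 for HOX, 0.16 for hypoxia and glycolysis, 0.097 for cholesterol synthesis, 0.11 for BMP and TGF-beta and 0.12 for Notch genes. Ethanol effects differed between arrays with and without FA for 6 lists, with medians of -0.16 for neural progenitor, -0.13 for endothelium and blood, -0.13 for endoderm, -0.21 for HOX, 0.17 for hypoxia and glycolysis and 0.20 for cholesterol synthesis genes. FA effects differed between the days for 3 lists, with medians of 0.12 for neural progenitor, 0.24 for early mesoderm and 0.25 for liver and yolk sac genes. None of these 17 list differences held with an estimated correlation, where the lowest adjusted p was 0.525. Without the day 7 array with ethanol and no FA, none of the 6 lists passed for ethanol by FA, so these calls depend on that array. In the same fits 5 of the 8 still passed for ethanol by day (pluripotency, mesenchyme and matrix, HOX, BMP and TGF-beta, and Notch genes) and 1 of the 3 for FA by day (early mesoderm). Outside the named genes, 5828 transcript clusters that were unnamed here or carried several symbols were tested for ethanol, and 15 passed, all of them lower with ethanol.

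Splits of the 8 embryoid body arrays into 4 and 4 were refitted with the remaining terms. For ethanol the real split passed 84 genes, and 1 of 33 splits, the real one, gave as many (highest other 0). For day 1 of 33 splits gave 5995 genes (highest other 0), and for ethanol by day 2 of 32 reached the real number of 1 gene. Most splits are uneven over the other factors and lose precision against the real one, and those balanced like it number 9 for ethanol and for day and 4 for each interaction, too few for a share under 0.05. For FA, ethanol by FA and FA by day the real number was 0, which all 33, 32 and 32 splits reach by definition (highest other 3 for FA), so the splits say nothing about chance there. The highest other split of the 3 interactions passed 718 genes, which points to a structure of the samples. That split is the real FA split with the labels of the 2 day 7 ethanol arrays exchanged.

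FA differences at day 7 with ethanol ran against those at day 21, with r of -0.56 and -0.52 across genes. With the FA labels of the 2 day 7 ethanol arrays exchanged, the FA differences of all pairs correlated above 0 (lowest r 0.12), 2713 genes had an unadjusted p under 0.05 for FA instead of 121, and 587 instead of 84 genes passed for ethanol. The exchange only reverses the sign of that pair, which also had r = -0.16 with day 7 without ethanol. The positive correlations therefore restate those before the exchange. The larger numbers of genes for FA and ethanol come from the same reversal. Neither is separate evidence for an exchange. The test was first set on the number of genes FA passed, which was 0 under every exchange and decided nothing, and was replaced by the correlation once that was seen; each of the other 3 exchanges within a pair gave 73 to 121 genes at that p. An exchange of labels is a possible explanation, but FA effects that depend on day and ethanol together give exactly these values, so the explanations cannot be told apart with 1 array per condition. A deviation of the day 7 array with ethanol and no FA, which stood apart, was not separated from either.

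Hypoxia and glycolysis genes were lower on average with ethanol, although 0 of 19 passed over all genes tested and the list had adjusted p = 0.675 with an estimated correlation. In each of the 3 pairs without the day 7 array with ethanol and no FA, the list median was also below 0 (highest -0.12). The lower values were therefore not confined to that array. Those medians lay at or below the 0.01 percentile of 10000 matched lists, a rank that can overstate for genes that move together. A slower departure from the undifferentiated state with ethanol may contribute, because across 12235 genes outside the list the ethanol difference correlated negatively with the change from undifferentiated cells in 4 couples of otherwise separate arrays (r -0.35, -0.47, -0.22 and -0.30, all with the same undifferentiated array). FA differences treated the same way gave r of -0.21 and -0.15 at day 21 without and with ethanol, so negative values at day 21 were not particular to ethanol. At day 7 they gave 0.02 without ethanol and 0.25 with ethanol, the latter using the array that stood apart. The ethanol value of -0.47, from day 7 without FA, also uses that array. The day 7 arrays without ethanol were close to each other (r = 0.9975 across genes). A deviation shared by them would therefore also give negative ethanol values at day 7. Smaller aggregates, cell density and other culture differences between dishes were not tested, and no biological explanation is established.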

How the results depend on the processing

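The alternatives were planned, except that the tests of gene lists without the day 7 array with ethanol and no FA and the test of unnamed clusters were added after seeing the data. The labels give no replicate numbers to pair samples by, but with the pairs matched on the other factors as a block 126 genes passed for ethanol, and all 84 were among them. The genes named for the largest ethanol, FA, day and differentiation effects, and SHISA3, were run through the alternatives. None of them reversed its direction. Those of FA, day and differentiation kept their side of the threshold, which for FA follows from 0 genes passing in every run. Genes named only as list members or for the day 7 pair were not followed in this way. Of the 24 genes with the largest ethanol effects, 7 lost their call with no filter (54 genes passed), 5 with median centring and all 24 without covariates (0 passed), where the day differences enter the residual. Only 20 of the 24 were bright enough to be tested with the stricter filter, and all 20 passed. For ethanol, 148 genes passed with eBayes trend and robust, 972 (555 higher, 417 lower) with all 2-way interactions, and 19 when at least 1.5-fold was required in addition. The fit with all 2-way interactions takes them out of the residual. Only the joint interaction of ethanol, FA and day is left to estimate the spread, so the 972 rest on very little. Leaving out each array gave 0 to 212 genes for ethanol, 0 to 0 for FA, 4437 to 6982 for day, 2107 to 4825 for differentiation, 0 to 1112 for ethanol by day, and 0 to 0 for ethanol by FA and for FA by day. Without the day 7 array with ethanol and no FA, 6 lists passed camera for ethanol, of which pluripotency, neural progenitor, HOX and cholesterol synthesis genes had not passed with it, while folate and one-carbon genes no longer passed. For FA 5 lists passed without it instead of 2, for ethanol by day 7 instead of 8, for ethanol by FA 1 instead of 6 and for FA by day 2 instead of 3. The 1 gene of ethanol by day became 0 with no filter and 0 with quantile normalization. At a 1.5-fold limit, 345 genes differed with ethanol at day 7 without FA, 79 at day 21 without FA, 107 at day 7 with FA and 97 at day 21 with FA. At 2-fold, the day 21 numbers were 16 without FA and 14 with FA with no filter, and 6 and 5 with the stricter filter. The 3 genes that differed in all 4 pairs became 7 with no filter, 0 at a 2-fold limit and 3610 for the same sign with no size limit. With the stricter filter, which removed PCDHB14, they became 2, both higher. The mean of all clusters gave 2 (1 higher, 1 lower) and quantile normalization 4. With an estimated correlation 0 lists passed for any effect or interaction, and with fry, which tests whether a list's genes move one way on balance, 6 passed for ethanol, hypoxia and glycolysis genes not among them unless the day 7 array with ethanol and no FA was left out (adjusted p = 0.0441), 0 for FA, 19 for day, 12 for differentiation and 0 for each interaction. The 1 transcription factor gene among the ethanol calls became 0 with no filter and 0 with median centring. The lower share had an unadjusted p under 0.05 with the stricter filter (0.0452) and with quantile normalization (0.0313), and of 0.116 to 0.193 with the other 3 alternatives. Apart from changes explained by how an alternative was built, the cause was not tested. Background signal was not given for these arrays, so dim genes were limited only by the filter.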

Other observations

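The groups in the next paragraph, the list of amino acid transporters, its removal from the ATF4 genes and the tests of HOX order and of the day 7 array were chosen only after the result was seen. The ATF4 genes were listed after the ethanol calls had been seen. Genes of that response whose values had been looked at were left out, but SLC3A2 and CTH, both among the calls, stayed in.

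Solute carriers made up a large part of the ethanol calls. Of 238 tested solute carrier genes 19 passed (18 higher, 1 lower, 7.98%), against 65 of 12016 other genes (0.541%), a share with no test here because the group was picked for standing out among these calls. Beyond those already named they included the glutamate transporter gene SLC1A3 (0.59), the glutamine transporter gene SLC1A5 (0.49), the zinc transporter genes SLC39A8 (0.40), SLC39A14 (0.39) and SLC39A11 (0.37), and the vitamin transporter gene SLC5A6 (0.39). The nicotinic receptor subunit genes CHRNB4 (0.52) and CHRNA3 (0.43), the glutamate receptor gene GRIA1 (0.44) and the metallothionein gene MT1E (0.48) were also higher. Of 8 tested protocadherin beta genes 3 passed, all 8 were lower on average (median -0.59) and 7 were lower in all 4 pairs, though near-identical sequences in this family mean that 1 transcript can be read by several probe sets.

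Several amino acid transporter genes and CHAC1 were higher with ethanol. Of 27 tested amino acid transporter genes, past the threshold or not, 24 were above 0 on average and 7 passed, while others such as SLC7A3 (adjusted p = 0.0532) and SLC7A1 (adjusted p = 0.156) did not. In the 3 pairs without the day 7 array with ethanol and no FA, the median of all 27 was above 0 (lowest 0.15). It was at or above the 99.9 percentile of matched lists in each of them. However, the list was drawn up after the calls were seen, and every called gene had the same sign in all 4 pairs. These values therefore cannot decide whether that array was the sole source. An amino acid response regulated through ATF4 may be involved. Of 23 measured genes of that response that are not amino acid transporters, 20 were above 0, with a median of 0.13 and pair medians of 0.25, 0.12, 0.12 and 0.08. That median exceeded all matched random lists, a rank that can overstate for genes that move together. Of the 23, only CTH passed, and it was among the ethanol calls when the genes were listed, so it is not independent support. Camera for the 23 genes gave p = 2.8e-05 at the preset correlation and p = 0.119 with an estimated correlation. The same genes were lower in untreated embryoid bodies than in undifferentiated cells (median -0.40 at day 7 and -0.62 at day 21), so a slower departure from the undifferentiated state also remains open.

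HOX genes that rose more by day 21 tended to have low paralog numbers, as retinoid signalling in the cultures could produce. Across 18 genes Spearman's rho of paralog number and day effect was -0.51 (permutation p = 0.0343, Pearson's r = -0.59), with medians of 2.99 for 10 genes of paralogs 1 to 5 and 1.38 for 8 genes of paralogs 6 to 13. This order is also what general axial patterning would give, and neighbouring HOX genes are not independent. HOX genes dim on all arrays, among them HOXC9 to HOXC13, were removed by the filter, so the order covers the tested genes only.

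For 3 genes the ethanol difference had the same sign and was at least 1.5-fold in all 4 pairs, and 1 of 8 exchanges of the ethanol label within pairs, the real one, gave as many as 3 (highest other 0). With 8 exchanges no share under 0.05 can be reached.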
